A study of Homo sapiens with 4 samples.

How the data were processed

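MeDIP DNA and input DNA of HCT116 wild-type cells and of the DNMT1 and DNMT3B double knockout were labelled by random priming and hybridised together, per the labels, with Cy5 on the MeDIP fraction and Cy3 on the input. The deposited scanner files came from Agilent Feature Extraction 8.5.1.1, per the file headers. The processed intensity of each spot in the deposited files is, per the file headers, background-subtracted, corrected for trends across the slide and scaled with 1 linear dye factor per channel, with no intensity-dependent dye correction. Mean and local background intensities are the deposited raw values of each spot. The deposited log10 ratio of each spot is red over green, that is MeDIP over input by the labels. The error column of the log10 ratio in the deposited files was treated as a score, because it holds 1000 where no error was given. The deposited value table of the series equals that log10 ratio at every promoter probe (largest difference 0.0, rounded to 1 digit), with column medians of -0.00037 and -0.0022 for WT and -0.00055 and -0.00080 for DKO on the first and second design. Its scale, centring and direction are therefore those of the scanner software. The genome build of the probe coordinates is not given in the sources used here, so coordinates are printed as the files give them.

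Values were computed as log2 of processed red over processed green signal and centred on the median of each array, with no loess or quantile step, since many promoters could shift one way. Control spots and spots called outliers in any channel of either array of a design were left out (149 probes on the first design and 10 on the second), which left 71837 probes. Saturated spots were kept; 123 to 937 probes per array were saturated in the MeDIP channel and 1 to 78 in the input channel. A core promoter was the set of probes from -1000 to +500 bp of the start site by the distance in the array annotation, with at least 3 usable probes, and its value was their mean. Promoters had a median of 4 probes and at most 10. A promoter with several gene names was counted once. The 16269 gene names in the files were updated through a RefSeq table of assembly GRCh38.p14, used for names alone; 9774 matched by accession, 3866 by symbol and 1466 by synonym, and 1163 kept the name in the files. No promoter lay on both designs, which cover different chromosomes, so no value could be compared between them.

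With 1 array per line and design there was no test, and the choices that follow were fixed before the data were examined unless stated. A promoter counted as lower in DKO with a WT value of at least 1, DKO minus WT of -1 or less and at least 75% of probes lower, and as higher with the mirror of these limits. Named promoters needed at least 4 probes with at least 75% changed in one direction: the 12 most negative differences among promoters of at least 1 in WT, the 5 most positive among those of at least 1 in DKO, and the 3 largest absolute differences of each gene list; to these came the 5 smallest absolute differences among promoters of at least 1.5 in both lines, without the condition on direction, and DNMT1 and DNMT3B. Where a threshold left no promoter, the same ranks were taken without it, which was the case for all ranks that had one. Some promoters named by this rule are not reported here and were not replaced. The 17 gene lists were set against 10000 random lists of the same size drawn from 20 bins of mean ratio, as a description of these arrays, and list medians have 95% intervals from 2000 bootstrap draws of their promoters. The pipeline was tested on simulated data, with probes of the real arrays shuffled and 200 promoters given a WT-only enrichment.

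Alternatives were normexp background correction (offset 50) on mean and background intensities and loess within arrays, both in limma 3.58.1 under R 4.3.3, the deposited value table, scaling by the median absolute deviation, probes well above background in both channels of both arrays, all probes naming a gene, a window of -500 to +200 bp with at least 2 probes, the median in place of the mean, at least 5 probes, thresholds of 1.5-fold and of 1.5 on the log2 scale, and other matching of random lists. Removal of the median of the surrounding 15 by 15 spots, a threshold of 0.3 and random lists matched on input brightness were added after the data were seen. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Precision is limited by the number of arrays. Median errors of the scanner software's own model were 0.20 on the log2 scale, and 8 control probes with at least 98 spots each had a median SD of 0.044 to 0.072 between spots of one array.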

Results

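Methylated DNA immunoprecipitation (MeDIP), which enriches sheared genomic DNA with an antibody against methylated cytosine, was hybridised to human promoter arrays from HCT116 cells. HCT116 is a colon cancer line with many methylated promoters. The wild-type line (WT) was set against its derivative, labelled a double knockout (DKO) of the DNA methyltransferases DNMT1 and DNMT3B. Most DNA methylation is known to be lost in DKO cells. On each array the MeDIP fraction carried Cy5 and total genomic DNA of the same line (input) carried Cy3. The promoters were split over 2 array designs, the first covering chromosomes 1 to 10 and the second chromosomes 11 to 22, X and Y. Each line was hybridised once to each design, 4 arrays in all, so no value below has a replicate, no p-value can be given, and the number of arrays limits the precision. The errors given are SDs between the probes of a promoter, unless marked as SE. The arrays held 37621 and 34375 promoter probes, and the share well above background in both channels was 96.8% in WT and 97.2% in DKO on the first design, and 99.0% and 98.8% on the second. Median input signal was 2212 in WT and 2760 in DKO on the first design, and 4442 and 3943 on the second, over local backgrounds of 49 to 56.

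The comparison of DKO with WT asks which promoters carried methylated DNA in WT that was lost in DKO. None of the 13306 core promoters measured (-1000 to +500 bp of the transcription start site) had a mean log2(MeDIP/input) of 1 or more in WT, and none had one in DKO. Counts of promoters lower in DKO and of promoters higher in DKO were therefore both 0 at the threshold of 1 on the log2 scale. The highest WT value was 0.60, at the olfactory receptor promoter OR2A4, and the highest DKO value was 0.56, at the promoter of the T cell cytokine IL2; both are named for their rank after the values were seen. DKO minus WT lay between -0.14 and 0.13 for the middle 95% of promoters, which corresponds to 0.911-fold to 1.09-fold. Over all promoters the difference ran from -0.78 to 0.48, with an SD of 0.069 and a median of 0.0046. In 200 promoters given a simulated WT-only enrichment of 1.5 on the log2 scale, 100% were recovered by the same thresholds, against 33.5% at an enrichment of 1.0 and 0% at 0.5. Beside the changed promoters, 8 others were called at 1.5, 1 at 1.0 and 0 at 0.5. Promoters that shared probes with a changed one were not set apart from these others. The enrichment was added to finished ratios of shuffled probes, so the recovery describes the thresholds alone. It does not show that the arrays could detect a real loss of methylation.

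Among single probes, 0.152% had a ratio of 1 or more in WT and 0.115% in DKO on the first design, and 0.0466% and 0.0320% on the second. Their SDs were 0.23 in WT and 0.22 in DKO on the first design, and 0.20 and 0.19 on the second. Across probes, which are not independent replicates, the ratio in WT correlated with the ratio in DKO by 0.745 on the first design and 0.789 on the second. MeDIP and input brightness on the same array correlated by 0.996 to 0.997. DKO minus WT was -1 or less at 96 of 71837 probes, of which 91 were not well above background in every channel, and 1 or more at 79 probes, of which 72 were not.

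**Figure D1:**
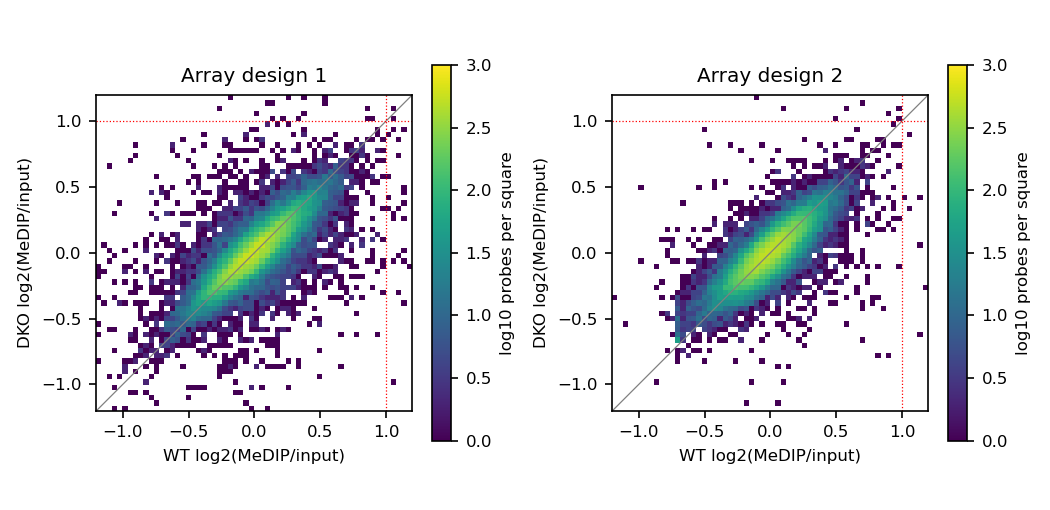
Ratio of each probe in WT (x axis) and DKO (y axis), both as median-centred log2(MeDIP/input), with colour giving the log10 number of probes per square, the grey line marking equal values and red dotted lines a value of 1. Probes lie along the line of equality in both designs (r = 0.745 and 0.789), and few reach 1 in either cell line; probes beyond 1.2 are outside the axes.

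No promoter passed the thresholds, so promoters were named by rank alone. Among promoters with at least 4 probes, of which at least 75% changed in one direction, the 12 lowest values of DKO minus WT ran from -0.56 to -0.37. LBR, which encodes the lamin B receptor of the inner nuclear membrane, had 0.30 ± 0.47 in WT and -0.26 in DKO over 4 probes (chromosome 1, 221922149 to 221923514). CD247, the zeta chain of the T cell receptor complex, had 0.48 ± 0.77 in WT and -0.076 in DKO (chromosome 1, 164219227 to 164220137), and 3 of its 4 probes were lower in DKO. CDH9, a cadherin, followed with a difference of -0.53 ± 1.5 over 5 probes, and OR2A7, an olfactory receptor, with -0.44 ± 0.70 over 5 probes. CD40LG, the CD40 ligand of activated T cells, differed by -0.40 ± 0.79 and LOC390535 by -0.40 ± 0.70. KIR2DL1, an inhibitory receptor of natural killer cells, differed by -0.38 ± 0.55 and LGSN, a lens protein gene, by -0.38 ± 0.89. The remaining promoters of this rank were SENP2, a SUMO protease gene, AGR2 and REG4, both expressed in secretory epithelia of the gut, and TEX13B, a testis-expressed gene, each with a difference of -0.37. All 12 differences were smaller than the SD between their own probes.

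Under the same conditions on probes, the 5 highest values of DKO minus WT ran from 0.38 to 0.48. C10orf67 had -0.23 ± 0.56 in WT and 0.25 in DKO over 5 probes (chromosome 10, 23673474 to 23674702). TAAR5, a trace amine-associated receptor gene, had -0.46 ± 0.55 in WT and -0.0054 in DKO over 4 probes (chromosome 6, 132952334 to 132953053). GTF2E1, a subunit of the general transcription factor TFIIE, differed by 0.45 ± 0.67, CD5L, a secreted macrophage protein gene, by 0.39 ± 0.65, and the zinc finger gene ZNF280C by 0.38 ± 0.74. Each of these 17 promoters held at least 1 probe that was not well above background. With probes well above background alone, the 11 of the 12 low promoters that kept 3 probes had differences of -0.17 to 0.12, and the sign turned at CDH9 (0.12) and LGSN (0.084). The 4 of the 5 high promoters that kept 3 probes then had 0.011 to 0.13. LBR kept 2 such probes and TAAR5 kept 1. With normexp background correction LBR had -0.088 and TAAR5 0.069. HSD17B12, HPN, PGLYRP3, LOC339483 and CREB3L3 had the 5 smallest absolute differences, and their ratios lay between -0.052 and 0.039 in both lines.

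Gene groups fixed beforehand were then compared as lists. The 17 list medians of DKO minus WT ran from -0.026 to 0.012, and no member of any list passed the thresholds. In WT itself the median ratio was -0.028 for genes reported as methylated in colorectal cancer. It was 0.032 for cancer-testis, 0.013 for autosomal germline and 0.043 for imprinted genes, against 0.0081 for housekeeping and 0.055 for ribosomal protein genes. The WT ratio thus did not set the groups known for methylation apart, so a small difference does not show that methylation was kept. Members named below had the largest absolute differences among those that met the same conditions on probes, so other members can lie further out. Genes reported as methylated in colorectal cancer had a median of 0.012 (95% bootstrap interval -0.0040 to 0.025) over 68 promoters, of which 30 were below 0 and 38 above. Within this list SOCS1, a suppressor of cytokine signalling, was at -0.20 ± 0.19 in WT and -0.066 in DKO, with all 4 probes higher in DKO. TAC1, which encodes tachykinin precursors, was at 0.21 ± 0.20 in WT and 0.083 in DKO, with all 5 probes lower. TCERG1L differed by 0.12 ± 0.077. Cancer-testis genes of the X chromosome, silent by methylation in most somatic cells, had a median of -0.0063 over 44 promoters, 23 below 0 and 21 above. Its named members were SSX3 (-0.15 ± 0.099), SSX2 (-0.12 ± 0.12) and SSX5 (-0.11 ± 0.13), at each of which all 4 probes were lower in DKO. Autosomal germline genes had a median of 0.00082 over 36 promoters, and their named members went both ways, with MAEL at 0.21 ± 0.21, DMRTB1 at -0.16 ± 0.088 and TUBA3C at 0.15 ± 0.11. Imprinted genes, methylated on one parental allele, had a median of 0.0080 over 26 promoters, with ATP10A at -0.12 ± 0.10, ZNF331 at -0.084 ± 0.077 and IGF2R at 0.079 ± 0.030.

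Olfactory receptor genes had a median of -0.023 (interval -0.036 to -0.012) over 241 promoters, 153 below 0 and 88 above. That median was below every one of 10000 random lists matched on mean ratio, whose middle 95% lay between -0.0028 and 0.014. Its named members were OR2A7 (above), OR4Q3 (-0.33 ± 0.27) and OR2T4 (0.29 ± 0.42). OR2A4, with 3 probes too few for the naming rule, had the lowest difference of the list, -0.54, and 1 of its probes was well above background. Keratin-associated protein genes, the other list outside the middle 95% of its random lists, had a median of -0.026 (interval -0.051 to 0.0023) over 31 promoters, at the 0.420 percentile. Its named members were KRTAP21-2 (0.17 ± 0.13), KRTAP2-4 (-0.15 ± 0.20) and KRTAP19-1 (-0.15 ± 0.25). With random lists matched on input brightness in place of the ratio, a setting added after the values were seen, the percentiles were 3.96 for olfactory receptors and 8.11 for keratin-associated proteins. With loess within arrays the olfactory receptor median was -0.0061.

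The remaining 15 lists, those of colorectal cancer, cancer-testis, germline and imprinted genes included, lay within the middle 95% of their random lists. Protocadherin cluster genes had a median of -0.024 over 10 promoters, with PCDHAC2 at -0.16 ± 0.21, PCDHB4 at -0.10 ± 0.11 and PCDHB6 at -0.045 ± 0.31. Ribosomal protein genes had a median of -0.0099 over 58 promoters, 37 below 0, with RPS24 at -0.36 ± 0.36, RPS23 at -0.19 ± 0.25 and RPS29 at 0.10 ± 0.44. At RPS29 4 of the 5 probes were lower in DKO, and the difference was -0.093 without its most extreme probe. Histone genes had a median of -0.0062, and H2AC8 with its divergent neighbour was at -0.19 ± 0.33, H4C3 at 0.12 ± 0.090 and H1-7 at -0.079 ± 0.037. Zinc finger genes had a median of -0.0012 over 225 promoters, with ZNF624 at 0.33 ± 0.63, ZNF549 at -0.20 ± 0.31 and ZNF800 at -0.15 ± 0.28. Homeobox and developmental transcription factor genes had a median of 0.0060 over 136 promoters, with IRX3 at 0.11 ± 0.12 and IRX4 at 0.10 ± 0.050. Interferon response and antigen presentation genes had a median of 0.0079, with HLA-DPA1 at -0.26 ± 0.37, CXCL9 at 0.13 ± 0.16 and IFI44 at -0.090 ± 0.095. Genes of intestinal differentiation had a median of -0.00061, and their named members were LCT (-0.13 ± 0.095), LYZ (-0.10 ± 0.077) and GUCA2B (-0.092 ± 0.060). Leukocyte genes had a median of -0.0036, with CD247 (above), IL2RA at -0.36 ± 0.55 and LYZ, which is in both lists. Housekeeping genes had a median of 0.0023, and SDHA (0.068 ± 0.14), CHMP2A (-0.067 ± 0.15) and COX4I1 (0.063 ± 0.085) were its named members. Genes of the methylation machinery had a median of 0.0076 over 11 promoters, with APOBEC1 at -0.086 ± 0.12 and UHRF2 at 0.060 ± 0.061. The microRNA list held 2 measured promoters, with a median of -0.0067, and MIR1915HG, a microRNA host gene, was at -0.041 ± 0.062.

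**Figure D2:**
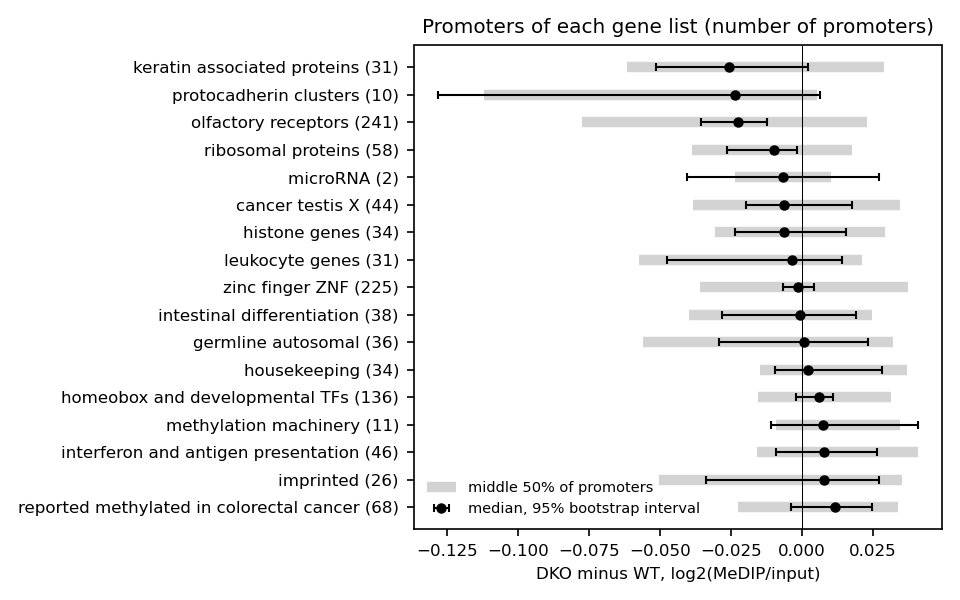
Median DKO minus WT of log2(MeDIP/input) over the promoters of each of 17 gene lists (points) with 95% bootstrap intervals (bars) and the middle 50% of promoters (grey), with the number of promoters in parentheses. The medians span -0.026 to 0.012; intervals cover the choice of promoters, not a repeat of the experiment.

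The targeted genes were looked at probe by probe. DNMT1 was covered by 4 probes (chromosome 19, 10166536 to 10171243), whose DKO over WT input ratio lay between -0.35 and -0.14 on the log2 scale, and its core promoter ratio was -0.0079 in WT and -0.00029 in DKO. DNMT3B was covered by 5 probes (chromosome 20, 30811190 to 30870474), with input ratios of -0.16 to 0.0037, and its core window held too few probes for a promoter value. The input ratios of both genes were not centred, so any difference in input brightness between the arrays is part of them. Over all probes of the second design the input ratio had an SD of 0.14. The labels do not say which exons were deleted, so these probes do not check the genotype.

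Around the transcription start site, mean ratios in 500 bp bins from -2000 to +2000 bp lay between -0.0075 and 0.021 in WT and between -0.0043 and 0.0097 in DKO. DKO minus WT ranged from -0.018 to -0.0075 in the bins outside -1000 to +500 bp. It was -0.012 ± 0.0016 (SE over 12270 probes) from -1000 to -500 bp. In the next 500 bp it was 0.0045 ± 0.00088 over 23979 probes (0.0011 with normexp). In the first 500 bp downstream it was 0.011 ± 0.00080 over 21494 probes. These SEs treat probes of the same arrays as independent, which they are not, so they do not test the differences. Each array was centred on its median, so the sign of a bin is relative to the other probes. DKO minus WT also correlated with input brightness, by 0.013 on the first design and 0.27 on the second. Whether brightness or slide position shapes this profile was not tested. Probes that the array annotation places inside genes had a median difference of 0.010, those in promoters 0.0018 and those in divergent promoters 0.0016.

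Neighbouring probes shared little of their ratio. Probes 150 to 300 bp apart correlated by 0.025 in WT, 0.021 in DKO and 0.0086 in DKO minus WT, over 40863 pairs, for which a correlation of 0 has a standard error of 0.0049. Probes that started less than 20 bp apart, and so largely overlapped, correlated by 0.306 in WT over 472 pairs. Those 20 to 60 bp apart correlated by -0.0061 over 483 pairs. Input brightness of the same pairs correlated by 0.686 below 20 bp and by 0.291 at 150 to 300 bp. The number of promoters with DKO minus WT of -0.3 or less was 44, against a mean of 43.1 when probes were dealt out at random among promoters in 100 shuffles, and the number at 0.3 or more was 32 against 34.2.

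**Figure D3:**
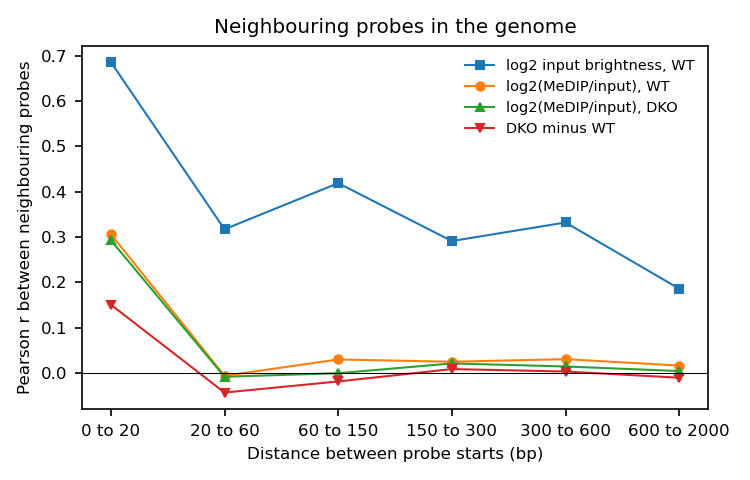
Pearson correlation (y axis) between neighbouring probes, by the distance between their starts in bp (x axis), for WT input brightness, the ratio in each line, and DKO minus WT. Brightness correlates by 0.291 at 150 to 300 bp, while the ratios correlate by 0.025 in WT and 0.021 in DKO at that distance.

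The input channel was compared along the chromosomes as a view of DNA dose, with the input ratio centred on the median of each design. Medians of log2 DKO over WT input per chromosome lay between -0.0092 and 0.011 on the first design and between -0.0072 and 0.010 on the second. Running medians over 51 probes ranged from -0.15 to 0.18 on the first design and from -0.077 to 0.067 on the second.

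DKO minus WT depended on where a spot lay on the slide. Spots side by side in a row whose probes lay on different chromosomes correlated by 0.228 on the first design and 0.278 on the second. Medians of blocks of 5 by 5 spots had a 5th percentile of -0.10 and a 95th percentile of 0.12 on the first design, and -0.13 and 0.092 on the second.

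**Figure D4:**
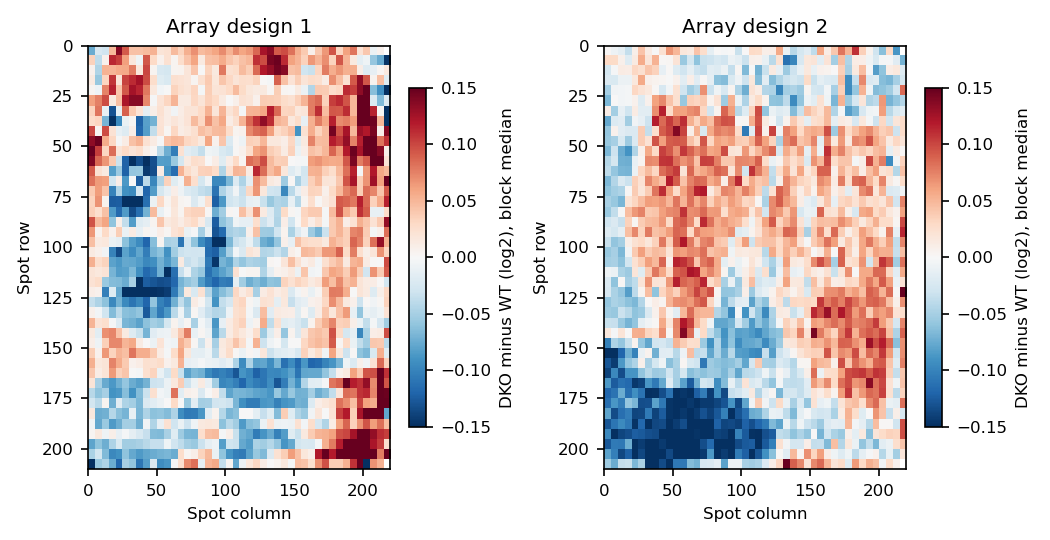
Median DKO minus WT of log2(MeDIP/input) in blocks of 5 by 5 spots, drawn by spot column (x axis) and spot row (y axis) for each array design; colours end at -0.15 and 0.15. Patches of low and high values extend over many blocks, with 5% of blocks below -0.10 on the first design and below -0.13 on the second.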

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

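The slide-position setting, the threshold of 0.3 and the matching on input brightness were chosen after the data were seen. The 4 promoter counts were 0 under every setting except lower thresholds. At 1.5-fold, 1 promoter was enriched in WT, OR2A4 with 1 of its 3 probes well above background. At a threshold of 0.3 the counts were 9 lower in DKO, 2 higher in DKO, 66 enriched in WT and 55 enriched in DKO; the pair of promoters higher in DKO were GTF2E1 and LPAL2, named, like OR2A4, after their values were seen. All 9 and both of these held a probe not well above background, and with probes well above background alone 0 were lower and 0 higher at 0.3. These counts grew because the threshold fell. Promoter values in WT spread no more than with probes dealt out at random (SD 0.107, against 0.106 to 0.109 in 100 shuffles). The enriched counts were not compared with such shuffles, so they are not counts of methylated promoters. Of 159 list medians recomputed, 154 stayed within their bootstrap interval and 5 left it: cancer-testis genes at 0.028 with at least 5 probes (6 promoters), developmental transcription factors at 0.016 and zinc finger genes at 0.0066 with the median over probes, zinc finger genes at 0.0052 in the shorter window, and olfactory receptors at -0.0061 with loess; the cause was not tested. Promoter values stayed within 1 SD between their probes in 621 of 622 recomputations, a wide margin at promoters with dim probes. The exception was TAAR5 at 0.069 with normexp. These recomputations include settings that left the probes of a promoter, and so its value, the same. Signs changed all the same at some named promoters. They changed at 6 of 67 in the shorter window, 5 of 69 with slide position removed and 4 of 69 with the median over probes. The named promoters include the 5 picked for the smallest absolute differences, where a sign means little. The 20 named promoters with at least 5 probes kept the same probes and values under that setting, so their signs could not change. With normexp, DKO minus WT around the start site ranged from -0.021 to 0.0081, with the sign kept in 8 of 8 bins. The value was within 1 SE over probes of the main one in 4 bins. From -500 bp to the start site it went from 0.0045 to 0.0011. Both settings use the same arrays and the SE does not cover a repeat of them, so a kept sign is not a replication. Ranges of chromosome medians of the input were 0.021 and 0.017, and 0.018 and 0.017 with raw signal over background. Correction for base composition was not run, as no probe sequence or genome was at hand, and leaving out replicates was not possible with 1 array per group. Signal over background limits the extremes: 1711 of 71837 probes were not well above background in every channel of both arrays.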

Other observations

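The tests in this part were chosen after the patterns were seen, while loess within arrays was a setting fixed beforehand. For random lists matched on input brightness, the bounds were set before the result of the test was known. The same holds for control spots against the promoter probes around them. For the other tests of this part the bounds were set afterwards, so those tests describe the values and were not predictions.

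In the 25% of probes with the brightest input, DKO minus WT correlated by 0.055 between probes 150 to 300 bp apart, and by 0.089 after removal of the local slide median, over 3529 pairs for which a correlation of 0 has a standard error of 0.017. Saturated spots were kept, and their part in these correlations was not tested. Control probes repeated on each array had a median SD of 0.044 to 0.072 between spots, against SDs of 0.19 to 0.23 between promoter probes. The control SD is between spots of the same probe, all well above background in the input channel. The other is between different probes, dim ones included, so the gap does not measure MeDIP signal.

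Neighbouring probes shared little of their ratio, with correlations small but above 0 at 150 to 300 bp, although the fragments of a MeDIP experiment span several probes. Wrong probe positions are argued against by the input brightness of probes starting less than 20 bp apart, which correlated by 0.686. For the WT ratio, dim probes are argued against by a correlation of 0.033 at 150 to 300 bp in the 25% with the brightest input. For DKO minus WT they are not, since its correlation was 0.0086 over all probes and 0.055 in that 25%. In DKO the ratio correlated by 0.021 over all probes and 0.046 in that 25%. Saturated spots were not set apart in that 25%. It was not tested whether probe sequence acted on the dyes or the MeDIP fraction on these arrays was weakly enriched. A loss of its signal in labelling or hybridisation was not tested either, and all of these stay open. A loss of methylation in DKO that the arrays could not show stays open too. Equal methylation of these promoters in both lines bears on DKO minus WT and was not tested. It would not by itself account for the low correlation within WT, 0.025 at 150 to 300 bp over all probes.

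DKO minus WT formed patches on both slides. Control probes repeated over the slide followed them: DKO minus WT of their spots, centred per probe, correlated with the local median of the promoter probes by 0.666 over 1198 spots of the first design and 0.733 over 1160 of the second (mean 0.700), in line with uneven hybridisation or scanning. Methylation differences would be shared in the genome rather than on the slide, and the correlation of genome neighbours minus that of slide neighbours was -0.24. Between spots side by side on the slide the ratio itself correlated by 0.080 in WT and 0.076 in DKO on the first design, and by 0.037 in WT and 0.121 in DKO on the second. The channel that carries the patches was not tested, and 1 array per line and design keeps array and cell line confounded.

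Olfactory receptor promoters lay below other promoters in DKO minus WT, with a median of -0.023 against 0.0046 over all promoters. The place of their spots is argued against, since the median was -0.024 after removal of the local slide median. A trend of the ratio with brightness may account for part of the shift: matched on input brightness, the list was at the 3.96 percentile, between the bounds set for and against this explanation, so the trend and a shift of these genes cannot be told apart by that test. With loess the median was -0.0061, against 0.0026 over all promoters, and lay at the 0.520 percentile of lists matched on mean ratio. Those lists were not matched on brightness, so they cannot tell whether loess removed the whole trend. Loss of methylation at these CpG-poor genes in DKO stays open and was not tested.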
